A study of Drosophila melanogaster with 2 samples.

How the data were processed

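ChIP-seq was done on chromatin of whole *Drosophila melanogaster* embryos, 0 to 16 hours old, from a line that stably expresses CG31388 with a C-terminal GFP tag. Per the labels, an antibody against GFP was used for the precipitation, DNA was fragmented by Bioruptor sonication to 200 to 800 bp, and the 2 libraries are biological replicates 2 and 4, each with technical replicate 1. They name different protocol documents, so a batch difference between them cannot be excluded and cannot be told apart from the replicate number. Both libraries form 1 group, and the control library was not analysed here.

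The authors deposited peak lists in the narrowPeak format on the dm6 and dm3 builds, 8 lists in all. Per the deposited read-me files, the list of each replicate was made from its alignments and 1 control alignment, the pooled list from the alignments of both replicates and the control, and the reproducible list from these 3 by the irreproducible discovery rate (IDR). The authors label the pooled list as peaks and background used as input for IDR. Its regions are called candidate regions here, and those that are not reproducible peaks can be background. The aligner, the peak caller and the IDR threshold are not given in the sources used here. The signal value of each region is the enrichment that the authors deposited, on a scale that the sources do not state. It was used to rank, describe and filter regions and to compare kinds of peaks within a list, and log2 signals of the peaks were correlated between the replicates. The deposited −log10 q-value reaches a ceiling in each list and was not used to rank. The deposited p-value column holds -1 throughout and was not used. On dm6 the pooled list has 28750 regions and each replicate list exactly 30000, so that ranks in the 2 replicates refer to lists of equal length. On dm3 the list of replicate 4 has 26320 regions and that of replicate 2 has 30000. Median widths were 400 bp in replicate 2, 390 bp in replicate 4 and 396 bp in the pooled list on dm6. Depth is unknown, so no error from read counts can be given. Intervals on shares of peaks or genes are 95% exact binomial (Clopper-Pearson) intervals and cover counting error only.

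Peaks were annotated with Ensembl release 115 genes on the same assembly as dm6, with all peak ends inside the arm lengths. Annotated transposable elements were left out as genes. Only the arms 2L, 2R, 3L, 3R, 4 and X were used, since the dm6 lists hold no others. A summit in the 500 bp on either side of any TSS was called promoter, and other summits were placed, in this order, in 5′ UTR, coding sequence, 3′ UTR, non-coding exon, intron or intergenic. Peaks were compared with the 26878 pooled candidate regions that are not reproducible peaks, by Fisher's exact test, two-sided. Odds ratios have Woolf 95% intervals, with 0.5 added to each cell where 1 cell was 0. A peak was matched to a replicate when its summit lay inside a region of that replicate. Signals of kinds of peaks were compared by the difference of medians with 100000 permutations, and correlations across peaks were tested the same way. For 26 gene lists, occupied genes were compared with all other protein-coding genes, or with all other genes for the tRNA and snRNA lists. Words of 7 bases on either strand were counted by presence in the 101 bp around each summit and in windows of equal width centred 300 bp to each side, and 10 motifs likewise. P-values were adjusted by the Benjamini-Hochberg method within each family, with a threshold of 0.05.

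Gene lists, motifs, tests and the rule for naming genes were fixed before the data were examined. The genes named are those nearest the 20 strongest peaks found in both replicates, the 4 strongest occupied members of each list past the threshold and up to 2 of each other list, the 5 peaks most shifted in rank towards each replicate, and CG31388. A few further names, such as the remaining architectural protein genes, were chosen after their values were seen. Alternatives planned beforehand were the 936 strongest peaks, the 1872 strongest regions of each replicate alone, promoter windows of 250 and 1000 bp, other backgrounds, other overlaps, a word window of 100 bp on each side, words of 6 and 8 bases, and dm3. Shuffled windows (4 per peak, with dinucleotide counts kept) and the divergent comparison within genes that have a candidate region were added after seeing the data. No coordinates were converted between builds.

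The tests were also tried on simulated data. With 13945 genes, the list of 86 cytosolic ribosomal protein genes was planted at 35% against 10%. The list was recovered in 100 of 100 simulations, and 7 of 2300 tests of unchanged lists were called. The planted shares were close to those observed, so the recovery adds no support for the real call. Genes were simulated as independent, whereas neighbouring genes share peaks. With 1872 simulated windows, no word was called without a planted word, and a word planted in 5% of the windows ranked 1 of 8192. The simulated summit and flank windows had the same GC content, unlike the real ones. This trial therefore does not cover calls that come from a difference in composition. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures matplotlib 3.10.9.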

Results

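The series measured where the protein of CG31388 sits on the *Drosophila melanogaster* genome. CG31388 belongs to the ZAD zinc finger genes, a fly family whose proteins carry a zinc-finger-associated domain before a row of DNA-binding zinc fingers. Whole embryos of mixed sex, aged 0 to 16 hours, came from a transgenic line in which the protein carries a green fluorescent protein (GFP) tag at its C-terminal end. Chromatin was sonicated and precipitated with an antibody against GFP, and the recovered DNA was sequenced (ChIP-seq). There was 1 group with 2 libraries, biological replicates 2 and 4, so the comparisons were between kinds of places in the genome and between the 2 replicates. Read depth was not given in the peak lists and is unknown here. All coordinates are on the dm6 build unless stated otherwise.

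The tagged protein had 1872 reproducible peaks, which covered 703 kb, or 0.525%, of the 6 assembled arms. They were 6.51% of the 28750 candidate regions called on the pooled libraries, which the authors label as peaks and background. The 1872 strongest of these regions by signal were the peaks themselves. The signal, which is the enrichment value the authors deposited for each region, ran from 53.8 to 771 with a median of 77.9, against a median of 20.5 in the other candidates. A small group stood above the rest, with 110 peaks over a signal of 200.

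The strongest peak lay 27 bp from a transcription start site (TSS) of *Ugalt*, the UDP-galactose transporter, at X:2703716-2704050, with a signal of 771. The second lay in an intron of *ush* at 2L:480916-481251, 1387 bp from the TSS of *cbt*, which encodes a zinc finger transcription factor, with a signal of 683. The third was at the promoter of CG14100 (3L:19590450-19590773, signal 672). These 3 peaks also ranked 1, 2 and 3 in each replicate. Next came the promoters of *px* (2R:22514149-22514461, signal 578), which acts in wing vein patterning, and of the arginine methyltransferase gene *Art3* (3R:15229365-15229700, signal 570). The *Art3* peak also covers the promoter of the mitochondrial ribosomal protein gene *mRpS10*. An intronic peak 1041 bp from the nearest TSS, that of CG11050 (2L:6612557-6612865, signal 522), ranked 6. The Polycomb group gene *ph-p* (X:2137169-2137534, signal 519), the RNA exonuclease gene *PNPase* (3R:31404519-31404816, signal 507) and the chromodomain protein gene *Chro* (3L:22878749-22879043, signal 496) followed, each at the promoter.

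The rest of the 20 strongest peaks lay near *CHMP2B*, *mRpL41*, *CenG1A*, *Lk6*, CG5611, CG13323, CG1888, *mRpL23*, CG9147, *GstE13* and lncRNA:CR44619, with signals from 483 down to 356. All but 4 of the 20 were at promoters. The exceptions were the intronic peaks near *cbt*, CG11050 and *Lk6* and an intergenic peak at 2R:13035198-13035471, 11942 bp from the nearest TSS, that of CG13323. The summits of the 3 strongest peaks were rich in A and T. The 61 bp around the *Ugalt* summit (X:2703849-2703909) read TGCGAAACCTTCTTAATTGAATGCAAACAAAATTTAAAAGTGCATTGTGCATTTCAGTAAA, with a GC content of 29.5%. Those around the *cbt* summit (2L:481045-481105) read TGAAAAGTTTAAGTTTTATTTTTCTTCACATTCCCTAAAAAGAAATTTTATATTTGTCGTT, at 21.3%. Those around the CG14100 summit (3L:19590596-19590656) read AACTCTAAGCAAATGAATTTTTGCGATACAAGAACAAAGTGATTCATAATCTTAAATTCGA, at 27.9%.

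Most peaks lay at promoters and almost none in coding sequence. A promoter was taken as the 500 bp on each side of any annotated TSS, and 1047 of the 1872 peak summits fell in one (55.9%, 95% exact interval 53.6 to 58.2), against 24.7% of the 26878 other candidates and 13.6% of the assembled arms. The odds ratio over the other candidates was 3.87 (95% interval 3.52 to 4.26, Fisher's exact test, two-sided, p = 1.63e-168). Only 2 summits lay in coding sequence outside promoters, or 0.107%, against 9.55% of the other candidates (odds ratio 0.0101, Benjamini-Hochberg exact adjusted p = 1.67e-74 over the 7 classes). The share was also lower in 3′ UTRs (17 peaks, 0.908% against 4.32%, exact adjusted p = 4.32e-17), in introns (576 peaks, 30.8% against 40.0%, adjusted p = 1.82e-15), between genes (210 peaks, 11.2% against 19.4%, adjusted p = 7.15e-20) and in 5′ UTRs (9 peaks, 0.481% against 1.11%, adjusted p = 0.00839). Non-coding exons did not pass the test (11 peaks, 0.588% against 0.982%, exact adjusted p = 0.109). A promoter summit counts in no other class, so the promoter excess by itself lowers the other shares. Outside promoters, introns held 576 of 825 peaks and 10749 of 20244 other candidates, a higher share in the peaks. Regions between genes held similar shares there (210 and 5206). Coding sequence (2 and 2566) and 3′ UTRs (17 and 1161) stayed lower. These shares outside promoters were not tested. Regions are not replicates, so these and all later p-values across regions or genes describe this set of peaks and not the spread between embryo collections. Among the 936 strongest peaks, with fewer peaks tested, the call for 5′ UTRs was lost (exact adjusted p = 0.0603), with an odds ratio of 0.383 against 0.431 in all peaks. On the regions of 1 replicate alone the odds ratio for coding sequence was 0.0173 in replicate 2 and 0.0204 in replicate 4, and that for 3′ UTRs, 0.203 in the peaks, was 0.133 in replicate 2, each past the threshold.

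The promoter share fell with the strength of the region. It was 69.0% among the 100 strongest regions of the pooled list (95% exact interval 59.0 to 77.9), 51.7% from rank 1001 to 1872, and 18.5% from rank 20001 to 28750. The median distance from summit to nearest TSS was 356.5 bp in the peaks and 1810 bp in the other candidates. A group of 214 peaks, 11.4%, lay more than 5 kb from any TSS.

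**Figure D1:**
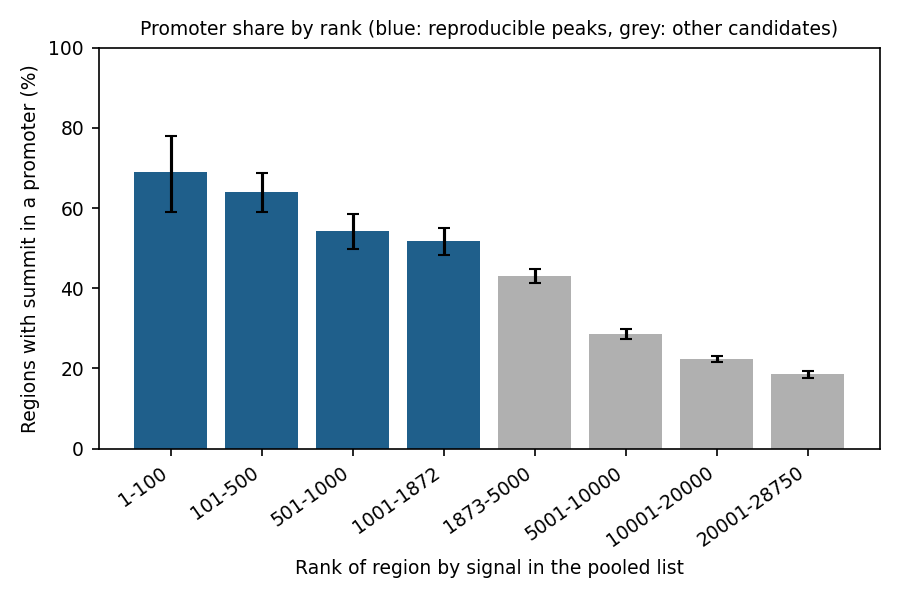
Share of regions with the summit in a promoter (percent, bars, with 95% exact intervals) by rank of signal in the pooled list of 28750 regions. Blue bars are the 1872 reproducible peaks and grey bars the other candidates; the share falls from 69.0% to 18.5%.

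Promoter peaks were slightly stronger than the others. The median signal was 81.5 in the 1047 promoter peaks and 74.8 in the 825 others, a difference of 6.75 (permutation test, two-sided, p = 0.00025). Promoter peaks were also more often among the 1872 strongest regions of both replicates, with 746 of them (71.3%) against 527 of the others (63.9%; odds ratio 1.40, 95% interval 1.15 to 1.70, Fisher's exact test, p = 0.00082). The same peaks were also compared by the signal of their region in 1 replicate, where it had one. The difference kept its direction, with 4.04 in replicate 4 (permutation p = 0.00059) and 1.39 in replicate 2, where it did not pass (permutation p = 0.0523). Signal scales differ between the lists, so the sizes of these differences are not comparable.

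The peaks were spread over all arms and were rare on the small chromosome 4. There were 376 peaks on 2L, 314 on 2R, 419 on 3L, 436 on 3R, 320 on X and 7 on chromosome 4. Chromosome 4, which is largely heterochromatic, held 0.374% of the peaks and 1.62% of the other candidates (odds ratio 0.228, 95% interval 0.108 to 0.481, Fisher's exact test, adjusted p = 8.09e-06 over 6 arms), or 5.19 peaks per Mb. On the regions of replicate 2 alone its odds ratio was 0.128 (exact adjusted p = 3.47e-10). X held 17.1% of the peaks against 14.9% of the other candidates (odds ratio 1.18, exact adjusted p = 0.033), and the shares on 2L, 2R, 3L and 3R did not pass the test. Against the share of annotated TSSs on each arm, neither chromosome 4 (odds ratio 0.483, exact binomial test, adjusted p = 0.0933) nor X (1.05, adjusted p = 0.602) passed, while 2R (0.771, adjusted p = 9.87e-05) and 3L (1.21, adjusted p = 0.00199) did. Against arm length 2R (0.866, exact adjusted p = 0.0393), 2L (1.18, adjusted p = 0.0142) and chromosome 4 (0.369, adjusted p = 0.0142) passed, and X did not (0.966, adjusted p = 0.606).

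The strongest sites ranked alike in the 2 replicates, and agreement fell down the list. Of the 100 strongest regions of replicate 2, 76 had their summit in 1 of the 100 strongest of replicate 4, and of all 30000 regions in each list 31.9% did. For the peaks, 1837 of the 1872 summits lay in a region of both replicates. Over these, the ranks in the 2 libraries had a Spearman's rho of 0.530 and the log2 signals a Pearson's r of 0.64, each across peaks, which are not independent (permutation p = 1e-05 for each, the smallest that 100000 permutations can give). The 1872 strongest regions of replicate 2 held 79.3% of the peaks and those of replicate 4 held 87.4%, a mean of 83.3% ± 5.74 (SD, n = 2). Both held 1273 peaks, and 25 were in neither. A single peak of the reproducible list can thus be weak in 1 replicate or lie in none of its regions. The peaks were chosen by IDR from the lists of these same replicates, so the agreement over the peaks is in part built in.

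Among the 1837 peaks found in both libraries, those most shifted in rank towards each replicate were taken separately, 10 in all. They had signals from 54.1 to 86.2, and all but 1 lay outside promoters. The promoter peak of CG11695 (rank 15357 in replicate 2 and 1063 in replicate 4) differed more than any peak named for replicate 2. The 10 are thus not the largest differences of all, and their places describe these 10 only. Ranked higher in replicate 2 were an intergenic peak near lncRNA:CR44619 (X:12755876-12756271, rank 714 in replicate 2 and 11209 in replicate 4) and intronic peaks near *fwe* (553 and 9965), *RhoGAP19D* (631 and 8396), lncRNA:CR33218 (777 and 8497) and CG6793 (710 and 8040). Ranked higher in replicate 4 were intronic peaks near lncRNA:CR46259 (2L:510437-510832, rank 29916 in replicate 2 and 616 in replicate 4), *MESR3* (28214 and 341), asRNA:CR43889 (28362 and 738) and *Piezo* (25030 and 1104), which encodes a mechanically gated ion channel, and the promoter peak of CG2201 (25997 and 869). With 1 library on each side, these differences have no replicate check. The peaks outside these 1837, some of them at promoters, had their summit in no region of 1 library and so have no rank there.

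**Figure D2:**
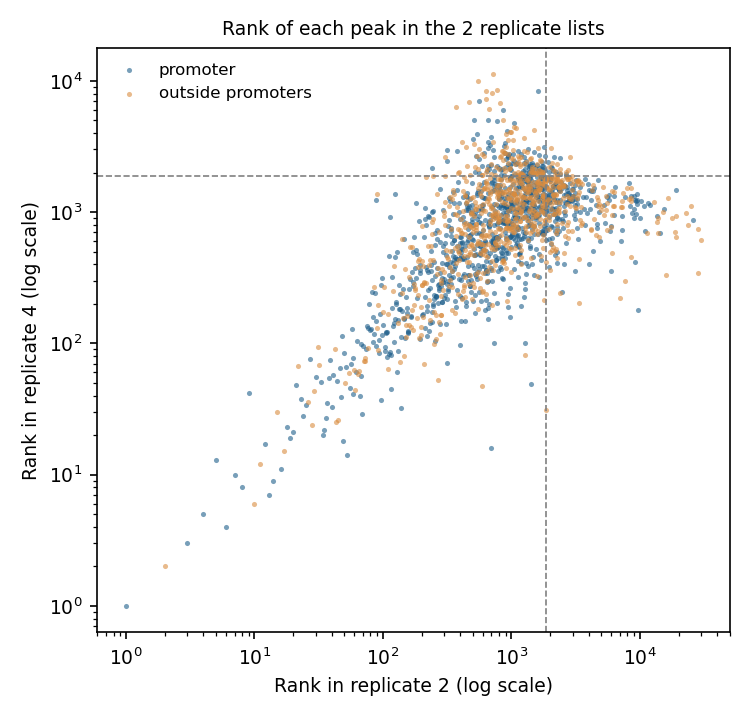
Rank by signal of each of the 1837 peaks found in both libraries, in replicate 2 (x axis) and replicate 4 (y axis), on log scales, coloured by place. Dashed lines mark rank 1872; the strongest peaks lie near the diagonal and the scatter widens towards lower ranks.

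Genes of the cytosolic ribosome had a peak at the promoter more often than other genes. Among 13945 protein-coding genes, 1411 (10.1%) had a peak summit within 500 bp of a TSS, and are called occupied here. Of the 86 cytosolic ribosomal protein genes, 30 were occupied (34.9%, 95% exact interval 24.9 to 45.9; odds ratio 4.84, 95% interval 3.10 to 7.57, Fisher's exact test, adjusted p = 1.27e-08 over 26 lists). The strongest were *RpS27* (signal 183), *RpL34b* (136), *RpL23A* (126) and *RpL7* (118). The *RpL7* peak ranked 181 in replicate 4 and only 9653 in replicate 2. The odds ratio was 2.61 on the 1872 strongest regions of replicate 2 alone (exact adjusted p = 0.00355), where 19 of the 86 genes were occupied, and 5.49 on those of replicate 4, where 32 were. A candidate region of any strength was present at 74 of the 86 genes, against 6482 of all coding genes (46.5%), and among genes with one the odds ratio was 2.48 (exact adjusted p = 0.00341).

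Genes for architectural proteins, which bind insulators and domain boundaries, were occupied in 10 of 26 cases (38.5%, odds ratio 5.58, 95% interval 2.53 to 12.3, exact adjusted p = 0.000548). The strongest were *Chro* (signal 496), *Cp190* (202), the condensin gene *Cap-H2* (108) and *M1BP* (93.7). The other occupied members were *row*, *pita*, *BEAF-32*, *Trl*, *pzg* and *Dref*. The summit of the *Trl* peak lay in no region of replicate 2. This call was lost on the regions of replicate 2 alone (odds ratio 2.18, exact adjusted p = 0.377), and with each peak given to its nearest TSS at any distance (odds ratio 2.74, adjusted p = 0.0988). Subunits of Mediator and RNA polymerase II, the general machinery of mRNA transcription, were occupied in 10 of 38 cases (26.3%, odds ratio 3.19, 95% interval 1.55 to 6.58, exact adjusted p = 0.0136), led by *MED27* (signal 156), *MED30* (134), *MED17* (123) and *Polr2B* (119). *Cap-H2* and *MED7* share 1 peak, and so do *Dref* and the cytosolic ribosomal protein gene *RpL13*. Divergent and other genes were not kept apart for the architectural and Mediator lists. The Mediator call was lost when only genes with some candidate region at the promoter were compared (odds ratio 2.12, exact adjusted p = 0.239), and with the nearest TSS (2.06, adjusted p = 0.206).

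Chemosensory, cuticle and tRNA genes were occupied less often than other genes. None of 179 chemosensory receptor genes (upper exact limit 2.04%, adjusted p = 1.29e-07) and none of 117 cuticle genes (3.10%, adjusted p = 4.78e-05) was occupied. Of 290 tRNA genes 4 were (1.38%, odds ratio 0.152 over all annotated genes, exact adjusted p = 4.08e-06), at *tRNA:Tyr-GTA-1-8* (signal 188), *tRNA:His-GTG-1-3* (76.0) and the neighbours *tRNA:Asp-GTC-1-5* and *tRNA:Asp-GTC-1-4*, which share 1 peak. The 111 histone cluster genes, which are repeated, had no candidate region of any strength, so that none could be occupied and the passed test of this list (exact adjusted p = 5.55e-05) is not informative. Among genes with a candidate region the lower share held for tRNA genes (exact adjusted p = 1.47e-05) and did not pass for chemosensory (odds ratio 0.124, adjusted p = 0.232) and cuticle genes (0.0968, adjusted p = 0.112). Only 14 chemosensory and 18 cuticle genes had a candidate region, and none of these was occupied.

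The other 19 lists did not pass the threshold. The ZAD zinc finger genes themselves were occupied in 10 of 63 cases (15.9%, odds ratio 1.68, exact adjusted p = 0.362), led by CG1792 (signal 249) and CG18476 (107). The trithorax group had 5 of 21 (23.8%, exact adjusted p = 0.176), among them the chromatin remodeller gene *brm* (195) and *Rbbp5* (91.1), and the Polycomb group 4 of 19 (21.1%, adjusted p = 0.343), with *ph-p* (519) and *E(z)* (97.5). The mitochondrial ribosomal protein genes had 11 of 73 (15.1%, exact adjusted p = 0.374), and among these *mRpS10* (570) and *mRpL41* (472) had far stronger peaks than any gene of the cytosolic ribosome. Respiratory chain and ATP synthase genes had 12 of 84, with *ND-24* (130) and *ND-ASHI* (115). Translation factors had 8 of 53, with *eIF6* (261) and *eIF4EHP* (202). Heat shock protein genes had 5 of 26, with *Hsp27* (217) and *Hsc70-5* (104). Aminoacyl-tRNA synthetases had 5 of 33, with *IleRS* (127) and *GluProRS* (121). Replication and cell cycle genes had 6 of 51, with *Cdc16* (121) and *Cdk12* (109). Spliceosome protein genes had 3 of 32, with *U2af50* (108) and *Sf3b6* (76.9), and proteasome subunits 3 of 48, with *Rpn3* (91.2) and *Rpn5* (82.6).

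None of the developmental lists passed in the promoter window. Muscle genes had 5 of 27 (18.5%, odds ratio 2.02, exact adjusted p = 0.374), with *mbc* (signal 122) and the heart transcription factor gene *tin* (100.1), neural genes 3 of 30, with *elav* (173) and *moody* (120.4), and signalling pathway genes 3 of 39, with the EGF receptor ligand gene *spi* (143) and *shn* (70.7). Segmentation genes had 1 of 30, *bcd* (57.0), and Hox genes none of 8 (upper exact limit 36.9%). The piRNA pathway had 3 of 34, with *papi* (132) and *cuff* (71.3), and snRNA genes 2 of 32, at the neighbours *snRNA:U6:96Ac* and *snRNA:U6:96Ab*. The eggshell list had 1 of 17, which was *Cp190*, an architectural protein gene and not an eggshell gene, taken in by the symbol pattern of the list. With each peak given to its nearest TSS at any distance, the muscle (odds ratio 4.58, exact adjusted p = 0.00345) and signalling lists (4.07, adjusted p = 0.00135) passed as well. A gene with many TSSs or distant neighbours takes in more peaks under this rule, and that was not corrected for.

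**Figure D3:**
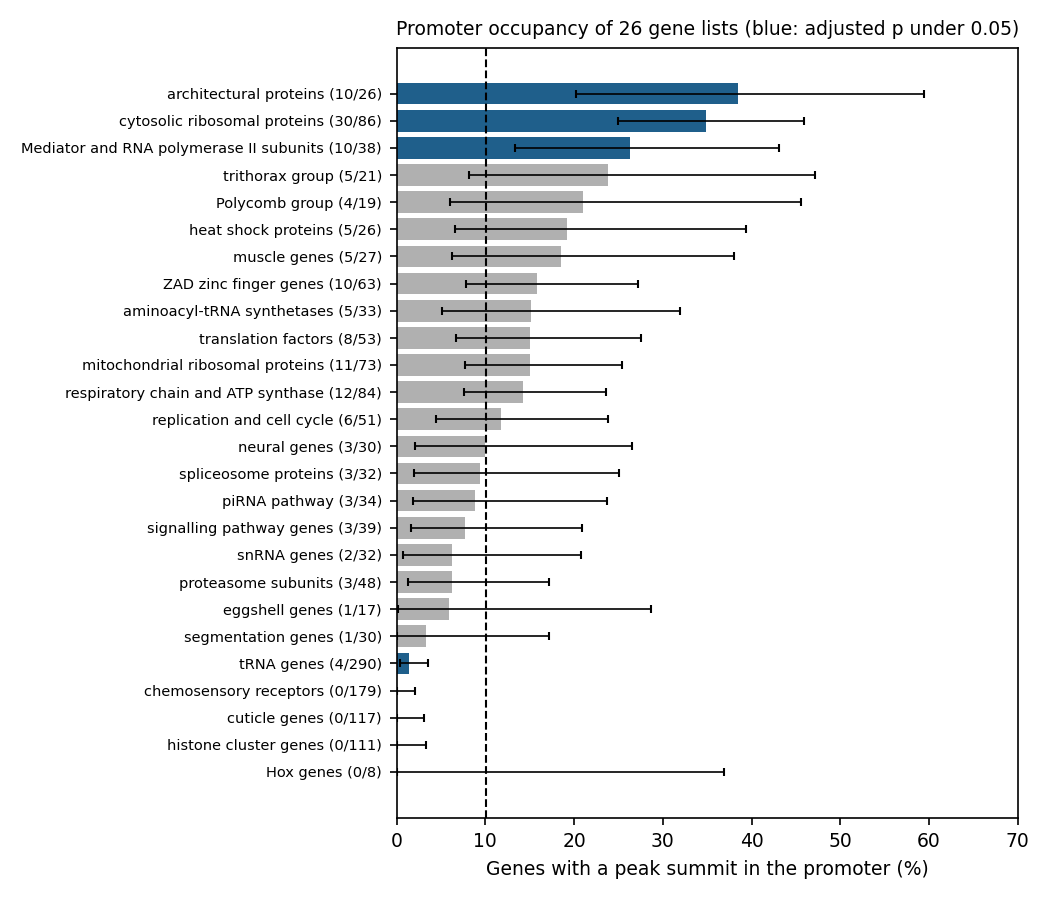
Percent of genes with a peak summit in the promoter in each of 26 lists, with occupied and total genes in brackets and 95% exact intervals. Blue bars passed the threshold, as did the chemosensory, cuticle and histone lists at 0, of which the histone genes had no candidate region; the dashed line is the 10.1% of all protein-coding genes.

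Divergent promoters held most of the occupied genes. A gene counted as divergent when another coding gene started head to head with it within 1000 bp. Of 5052 such genes 974 were occupied (19.3%, 95% exact interval 18.2 to 20.4), against 437 of 8893 others (4.91%, 4.47 to 5.38; odds ratio 4.62, 95% interval 4.10 to 5.21, Fisher's exact test, p = 6.22e-154). Neighbouring genes share peaks and are not independent. Among genes with any candidate region at the promoter, a comparison chosen after seeing the data, the odds ratio was 2.62 (exact p = 3.88e-54).

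Peak summits were poor in G and C. The mean GC content was 32.7% in the 101 bp around the summits and 44.4% in windows centred 300 bp to each side, and the median at the summit was 30.7% in promoter peaks and 31.7% in the others, against 40.6% in other candidates. Words of 7 bases followed this composition. Of 8192 words, 954 were more frequent at summits than in flanks and 1611 less frequent, led by AAAATAT, which occurred at 17.9% of summits and in 5.93% of flanks (odds ratio 3.46, Fisher's exact test, adjusted p = 1.23e-38). Against shuffled summit windows that keep the counts of neighbouring base pairs, chosen after seeing the data, 141 words were more frequent. These were led by ACAGTGG (58 peaks, 3.10% against 0.467%, odds ratio 6.81, exact adjusted p = 3.19e-15), whose odds ratio over flanks was 1.84, and among the first 10 were AAAATAT, CACAGTG, CAGTGTA, CACTGAG, ATCGATA, CGCCATC and GGCGCCA.

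**Figure D4:**
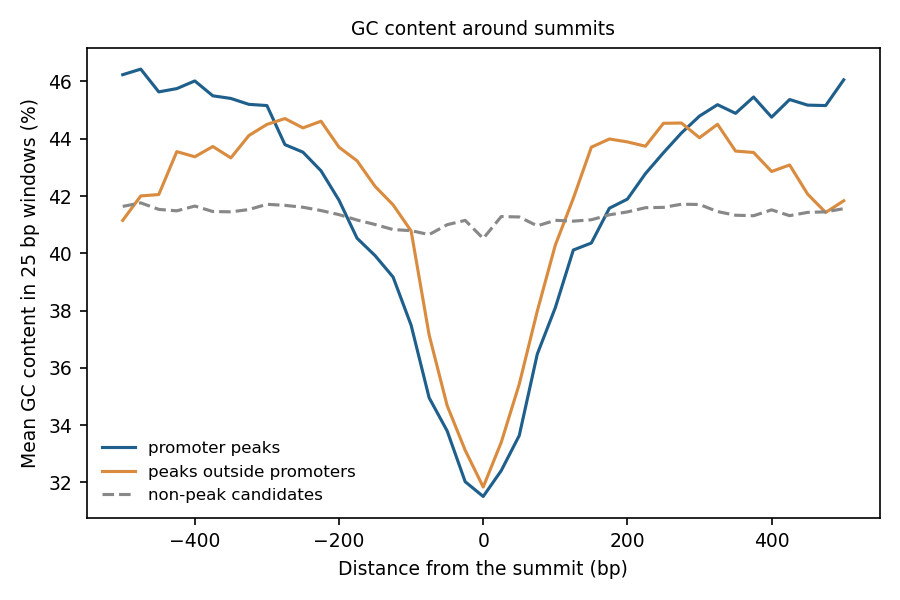
Mean GC content (percent) in windows of 25 bp by distance from the summit (bp), for promoter peaks, peaks outside promoters and non-peak candidates. Both kinds of peak drop to 31.5% and 31.8% at the summit, and the non-peak candidates stand at 40.5% there.

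Among 10 known motifs, the core of the CTCF insulator motif (AGGKGGCGC, where K is G or T) had the highest odds ratio over flanks. It occurred at 21 summits, or 1.12%, and in 4 flank windows, or 0.107% (odds ratio 10.6, 95% interval 3.64 to 30.9, Fisher's exact test, adjusted p = 8.21e-07). On the regions of replicate 2 alone the odds ratio was 4.69, from 14 summits and 6 flank windows (exact adjusted p = 0.00289). It was also more frequent than at the summits of other candidates (0.208%, odds ratio 5.43, exact adjusted p = 6.36e-08). The DNA replication-related element (DRE) TATCGATA, bound by Dref and BEAF-32, occurred at 23 summits (1.23% against 0.507%, odds ratio 2.44, exact adjusted p = 0.00939), and all 23 were at promoters. The TATA word TATAAA was at 452 summits (24.1% against 9.91%, odds ratio 2.89, exact adjusted p = 2.43e-42), and the GAGA motif (21 peaks, 1.12% against 4.11%, odds ratio 0.264, adjusted p = 4.24e-10) and the E-box CAGCTG (53 peaks, 2.83% against 5.48%, odds ratio 0.503, adjusted p = 1.28e-05) were less frequent at summits than in flanks. The words CGATA, motif 1 (GGTCACAC), the Zelda word CAGGTAG, the Su(Hw) core TTGCATAC and the initiator TCAGTY did not pass. The Su(Hw) core passed on the regions of replicate 2 alone (odds ratio 2.63, exact adjusted p = 0.0206), and CGATA with a window of 100 bp on each side (1.27, adjusted p = 0.000571) and against shuffled windows (1.34, adjusted p = 0.000891). Motif 1 turned from 0.869 over flanks to 5.02 against shuffled windows and passed there (exact adjusted p = 0.0015). The CTCF core and the DRE, which passed in both, had far higher odds ratios against shuffled windows (84.9 and 15.5), where 1 and 6 windows held them. Against shuffled summit windows the TATA word did not pass (odds ratio 1.06, exact adjusted p = 0.378) and GAGA (2.92) and the E-box (1.87) turned to more frequent, and against the summits of other candidates GAGA did not pass (exact adjusted p = 0.599). The DRE call was lost among the 936 strongest peaks (exact adjusted p = 0.647) and on replicate 2 alone (adjusted p = 0.213).

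No motif separated strong from weak peaks. Of 11 comparisons of signal between peaks with and without a motif or the leading word, none passed after adjustment. The smallest adjusted p was that of the TATA word, with a median signal of 82.6 in 452 peaks that had it and 76.8 in 1420 that did not (permutation p = 0.00794, adjusted p = 0.0873). Peaks with the CTCF core had a median of 70.8 against 78.0 (permutation adjusted p = 0.68).

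The gene of the tagged protein had no region of its own at the promoter. CG31388 lies on the plus strand at 3R:11237815-11240114. Within 20 kb of it there were 14 candidate regions, of which 1 was a reproducible peak. This peak lay 106 bp from the TSS of CG17726 at 3R:11226556-11226776, with a signal of 274 and rank 52, and ranked 55 in replicate 2 and 46 in replicate 4. The nearest candidates on each side of the gene lay near CG17721 (3R:11235517-11235912, signal 22.0) and CG17734 (3R:11242913-11243308, signal 42.7), and neither was a reproducible peak.

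The authors also gave the lists on the older dm3 build, which held 1818 reproducible peaks, 0.971 times the number on dm6. Counts per arm were 365 on 2L, 305 on 2R, 407 on 3L, 425 on 3R, 308 on X and 7 on chromosome 4, with 1 more on the scaffold 2RHet. The strongest signal was 771 on both builds.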

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

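The dm3 lists hold regions on scaffolds outside the 6 arms, which the report's comparisons do not use. The pooled dm3 list had 114 such candidate regions, with 38 on 3LHet, 31 on 3RHet, 30 on 2RHet, 5 each on 2LHet and U, 4 on XHet and 1 on Uextra. Their median signal was 20.5. One of them was a reproducible peak, at 2RHet:1005370-1005765 on dm3, with a signal of 88.2 and rank 714 of the pooled dm3 list. The strongest region on 2RHet ranked 1402 in replicate 2 and 542 in replicate 4. A test of 1 library against the others of its group needs more than 2 libraries.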

How the results depend on the processing

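Among the alternative values of the main results, 55 kept their direction and side of the threshold or stayed within 1.5 times the main count. Of the rest, 8 counts moved further and 1 difference fell below the threshold, and the cause was not tested unless stated. Counts were compared by size alone, so a count that stayed can stand for other tests passed. The arms past the threshold were chromosome 4 and X against the other candidates. They were 2R and 3L against TSSs, and 2R, 2L and chromosome 4 against arm length. The difference in median signal between promoter and other peaks was 1.39 to 4.04 with the signals of single replicates on the same peaks. Their signal scales differ, and the difference did not pass with those of replicate 2. Among the 936 strongest peaks, 1 arm passed in place of 2 and 625 words were enriched in place of 954. Enriched words numbered 549 at promoter peaks only and 473 outside promoters, where fewer peaks were tested, 439 for words of 6 bases, of which there are fewer, and 141 against shuffled windows (added after seeing the data), which hold the composition constant. Gene lists past the threshold fell from 7 to 3 when only genes with a candidate region were compared, with fewer genes tested, and candidate regions near CG31388 rose from 14 to 32 within 50 kb, a longer stretch. Among values of single arms, classes, lists, motifs and peaks, 381 stayed as they were, 7 passed the threshold newly, 14 lost it, 1 moved and 7 reversed. X had an odds ratio of 0.966 against arm length and 3L 1.21 against TSSs, and the signalling list 4.07 with the nearest TSS. Against shuffled windows motif 1 had 5.02, GAGA 2.92 and the E-box 1.87. The DRE had 0.285 outside promoters, from 0 summits and 3 flank windows, and did not pass there (Fisher's exact test, adjusted p = 0.793). No paired analysis was possible because there is 1 group. Unknown read depth limits any statement on weak regions.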

Other observations

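The tests on fragment composition, the use of tRNA genes as a test of capture, the test of divergent genes among those with a candidate region, the comparisons between replicates, and the values on clusters, transposable elements and words were chosen after the results were seen. Some genes held several peaks, and their length was not taken into account. CG1677 (X:7281089-7405797) had 11 peak summits within the gene, *Raf*, the MAP kinase kinase kinase gene, had 7, *CHES-1-like*, *kirre* and *ush* had 6 each, and *Eip75B*, *Tlk*, *rdx* and *sbb* had 5 each. In all, 53 coding genes had 3 or more. Neighbouring peaks lay less than 2 kb apart in 187 cases, against a median of 72 and a highest count of 101 in 1000 random draws of 1872 candidate regions. The draws were not matched for promoters, which held 55.9% of the peaks and 24.7% of the other candidates, so promoter location may account for the excess. Transposable elements held 4 summits (0.214%, against 1.05% of other candidates, odds ratio 0.201, 95% interval 0.0749 to 0.54, Fisher's exact test, p = 5.62e-05).

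A CTCF-like core with either purine at the third base (AGRKGGCGC, where R is A or G) occurred at 42 summits, 2.24%, against 0.214% of flanks (odds ratio 10.7, 95% interval 5.02 to 22.9) and 0.499% of other candidates (odds ratio 4.58, 3.23 to 6.50). Of these 42 peaks, 25 lay outside promoters. The word CCACTGT, the other strand of the word ACAGTGG that led against shuffled windows, occurred at 58 summits, 3.10%, against 1.71% of flanks (odds ratio 1.84, 1.28 to 2.63, Fisher's exact test, p = 0.00125) and 1.72% of other candidates (odds ratio 1.83, 1.39 to 2.42). Both words were picked from these same peaks. Around CG31388, 60.4% of other coding genes had fewer than its 14 candidate regions within 20 kb, and the median was 12.

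The low GC content at summits was weighed against the promoter content of the peaks and a preference of the libraries for AT-rich fragments. Promoters alone do not account for it, since outside promoters the median of summit minus flank was -12.4 percentage points in peaks and 0.495 in other candidates, a difference of -12.9 (permutation p = 1e-05, the smallest possible). A preference for AT-rich fragments stays open, since the difference from other candidates depends on the window chosen within the 200 to 800 bp of the fragments, and outside promoters it was -5.97, -2.00, -0.166 and 0.749 points within 100, 200, 300 and 400 bp of the summit (permutation p = 1e-05 for the first 2, the smallest possible, then 0.72 and 0.00582). It was -6.47, -2.99 and -1.33 points in promoter peaks and -6.47, -2.99 and -0.998 points in all peaks within 100, 200 and 300 bp (permutation p = 1e-05 for each), and -0.25 (p = 0.362) and 0.125 points (p = 0.702) within 400 bp. The 211 peaks strong only in replicate 2 and the 363 strong only in replicate 4 had median GC contents of 29.7% and 35.6% at the summit (permutation p = 1e-05, the smallest possible) and of 40.3% and 40.9% within 400 bp (a difference of -0.624 points, permutation p = 0.215). These p-values are over peaks, and with 1 library on each side the difference has no replicate check. No biological explanation was tested.

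The occupied ribosomal protein genes were weighed against unspecific capture of strongly transcribed DNA and against their place in divergent pairs. The tRNA genes, taken as strongly transcribed, were occupied less often than other genes among those with a candidate region (odds ratio 0.145, 95% interval 0.0532 to 0.393). This gave no sign of capture of DNA transcribed by any polymerase. The test cannot exclude such capture, since expression was not measured and a candidate region near a tRNA gene can belong to a neighbouring gene. An effect limited to RNA polymerase II also stays open. The snRNA genes, the other list of highly transcribed short RNAs, decide nothing, with 15 genes that have a candidate region (odds ratio 0.626, exact adjusted p = 0.862). With divergent and other genes kept apart, the Mantel-Haenszel odds ratio of the list was 3.53 (95% interval 2.22 to 5.59), so that pairing alone does not account for it. The replicates differed here, with 17 ribosomal protein genes occupied only in replicate 4 and 4 only in replicate 2, against 347 and 356 other coding genes (odds ratio 4.36, 95% interval 1.45 to 13.1, Fisher's exact test, p = 0.00643). The p-value is over genes, and with 1 library on each side the difference has no replicate check. No biological explanation was tested.

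The excess at divergent promoters was weighed against the counting of 1 peak for both genes and against more candidate regions of any strength there. With windows of 1 width, counted once, 455 of 2518 pair midpoints held a peak (18.1%) against 338 of 8758 single TSSs (3.86%), an odds ratio of 5.49 (95% interval 4.73 to 6.38). A pair was placed at its closest TSSs and a single gene at its outermost TSS. Peaks at other TSSs were not counted, so the size of this odds ratio is not comparable with that per gene. Among genes with a candidate region the odds ratio was 2.62 (2.31 to 2.98), lower than the 4.62 over all coding genes, so that candidate regions account for part of it at most. A candidate explanation that was not tested is that divergent genes are more often active in these embryos, since expression was not measured here.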
